A study of Homo sapiens with 13 samples.

How the data were processed

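RNA-seq libraries of 13 samples were compared: 9 biopsies of blastic plasmacytoid dendritic cell neoplasm (BPDCN) from skin and 4 samples of normal plasmacytoid dendritic cells (pDCs) isolated from blood. Per the labels, total RNA of the biopsies was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA v2 kit. The authors deposited raw counts per gene symbol together with a gene length, and no normalization had been applied to these counts. STAR 2.4.0 and the hg19 build are named in the submitters' processing notes, while the counting tool, the annotation and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes, such as HSPA1A and HSPA1B or TPSAB1 and TPSB2, therefore cannot be assigned with certainty. No coordinates are given, since the reference used here was of another build.

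The table held 26473 genes, and every column of counts per sample was used (0 unused). Library totals ran from 13485309 to 74259874 counts. XIST and Y-linked genes (108 entries) were left out of all steps. The groups came from the labels, which give no batch, donor or pairing, and replicates were numbered only as names. P-values therefore measure the spread between these samples, which may be technical. Group and tissue of origin coincide, so no covariate can separate them; a score of skin markers adjusts only for what those markers measure in each library.

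Differences between the groups were tested with edgeR 4.0.16 in R 4.3.3 by the 2-sided quasi-likelihood F test after filterByExpr with its defaults (minimum count 10, minimum total count 15) and TMM scaling. P-values were adjusted by the Benjamini-Hochberg method over the 17894 genes tested, and genes with adjusted p under 0.05 were called. Fold changes are log2 of BPDCN over pDC. Their standard errors are approximate, computed as the absolute log2 fold change divided by the square root of F. Means and SDs are of counts scaled to TMM library size, in CPM, and log2 CPM used a prior count of 2. For a gene with 0 counts in all pDC libraries, a lower bound of the fold was computed against 3 counts over the pDC group. Such bounds cover counting error only.

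The 39 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the other settings listed next, except where said. Each list was tested with camera (limma 3.58.1, 2-sided, preset inter-gene correlation 0.01), adjusted over all lists, and members were also counted after adjustment over the list alone. The tissue score of a library was the mean of the keratinocyte, fibroblast and endothelial list means in log2 CPM. It was compared between groups by an exact 2-sided permutation test over all 715 splits. Pairs of libraries were compared by Spearman correlation and by a chi-square over genes with at least 50 counts.

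Named genes followed a rule with 4 parts. Part 1 was a fixed panel (CD4, NCAM1, IL3RA, TCL1A, CLEC4C, TCF4, BCL2, MYC, EZH2, TET2, ASXL1, DNMT1). Part 2 was the 5 highest and 8 lowest log2 fold changes among called genes whose groups did not overlap. Part 3 was the 8 highest of the higher genes that were also called higher with the tissue score as covariate. Part 4 was, in each list described, up to 2 called members with the largest positive and up to 2 with the largest negative change. Parts 2 and 3 left out immunoglobulin and T cell receptor segments, clone-named, LOC, MIR, SNOR and pseudogene entries, and genes with a mean log2 CPM below 1. For the arginine methyltransferase, chemokine receptor, ribosomal, and red cell and platelet lists the results give counts and list tests, and single members appear only in the additional observations. Some genes that the rule names are not reported here.

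The other settings were RLE size factors, upper-quartile scaling, library size alone, DESeq2 1.42.0, limma voom with sample weights, no low-count filter, a stricter filter (CPM above 1 in at least 4 libraries), glmTreat against a 2-fold change, the tissue score as covariate, omission of the genes of the other-cell lists, and each library left out in turn. List tests were also run with an estimated correlation and with fry, and the tissue score with prior counts of 0.5 and 5 and from each list alone. Removal of a smooth trend on gene length (loess span 0.5), the covariate fit without BPDCN replicate 9, and omission of BPDCN replicates 1 and 9 together were added after seeing the data. The interval over all 11 chromatin lists, the bounds of named genes with each tumour library left out of the mean, and the counts of changed signs were also added then. Intervals of list medians against all genes are 95% bootstrap intervals over members (10000 resamples), which are not independent. Other splits of the libraries into 9 and 4 were drawn with a fixed seed to a total of 100, the real one included.

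The test was tried on simulated counts for the 17894 genes with 200 genes changed. Of genes changed 2-fold it recovered 2%, and of genes changed 4-fold 47%, which missed the 50% first required. Simulations of 8-fold and 16-fold changes were added after that and gave 87.9% and 94.9%. False calls were 1.96% and 1.1% of calls in these simulations. The real comparison called 5131 genes higher and 3294 lower, far more than were changed here. The p-value that passes adjustment depends on that share, so these recoveries and false shares need not hold for the real data. A list shifted in the simulation was called (camera adjusted p = 4.57e-20) and 0 of 38 unshifted lists were, in simulated counts without correlation between genes. A simulated length trend with a slope of 1.38 was reduced to 0.0591.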

Results

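Blastic plasmacytoid dendritic cell neoplasm (BPDCN) is a rare blood cancer that often presents in the skin and is held to arise from the plasmacytoid dendritic cell lineage. Plasmacytoid dendritic cells (pDCs) are blood cells known for producing type I interferon when their Toll-like receptors meet viral nucleic acid. RNA sequencing was available for 13 libraries: 9 BPDCN tumours taken as skin biopsies before treatment, and 4 preparations of normal pDCs isolated from blood. The series title places the study around epigenetic regulation in this tumour. The design implies 1 comparison: which transcripts differ between the tumours and their presumed normal counterpart. The deposited values were raw read counts for 26473 gene symbols, with totals of 13485309 to 74259874 counts per library. Tissue of origin coincided with group, since every tumour library came from skin and every pDC library from blood. Nothing in the labels stated that the libraries of a group came from separate donors, so p-values measure the spread between these libraries.

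The tumours and the normal pDCs differed across a large part of the transcriptome. Of 17894 genes tested, 5131 (28.7%) were higher and 3294 (18.4%) were lower in BPDCN (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among them, 4731 rose and 2662 fell by 2-fold or more. The groups did not overlap for 4661 of the genes tested, a separation that a gene shows by chance in 0.280% of splits, and 2363 of the higher and 2161 of the lower genes were among them. The median log2 fold change of all genes was 0.21, and it was 0.41 under upper-quartile scaling and 0.37 with library size alone. With a score for skin tissue as a covariate, 1102 genes were called higher and 459 lower, of which 1048 and 358 were also called without it. Testing against a minimum change of 2-fold (glmTreat) left 3266 higher and 1090 lower genes.

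**Figure D1:**
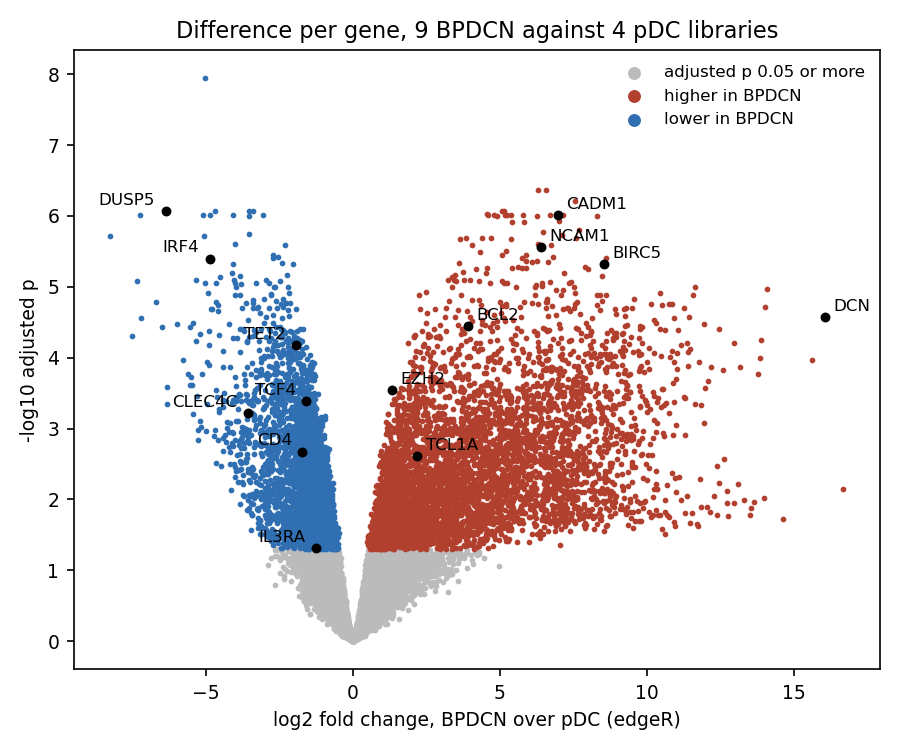
Each point is a tested gene, with the log2 fold change of BPDCN over pDC on the x axis and minus log10 of the adjusted p on the y axis. Red points were called higher (5131 genes), blue points lower (3294 genes) and grey points not called, and black points mark labelled genes such as NCAM1 at 6.40 and IRF4 at -4.87.

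The libraries separated by group along the first principal component, which held 58.2% of the variance. The 4 pDC libraries were close to each other, with Spearman correlations of 0.981 to 0.989 between pairs. Tumour pairs spread more widely, from 0.80 to 0.957. BPDCN replicate 9 lay between the other tumours and the pDCs on that component, with a score of 67.7 against -128.6 to -75.3 in the other 8 tumours and 172 to 204 in the pDCs. Its Spearman correlations were 0.904 to 0.913 with the pDC libraries and 0.80 to 0.882 with the other tumours, which had 0.78 to 0.842 with the pDCs. Without this library 5774 genes were called higher and 4106 lower. No pair of libraries agreed within sampling noise, since the smallest chi-square per degree of freedom between replicates was 53.8.

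**Figure D2:**
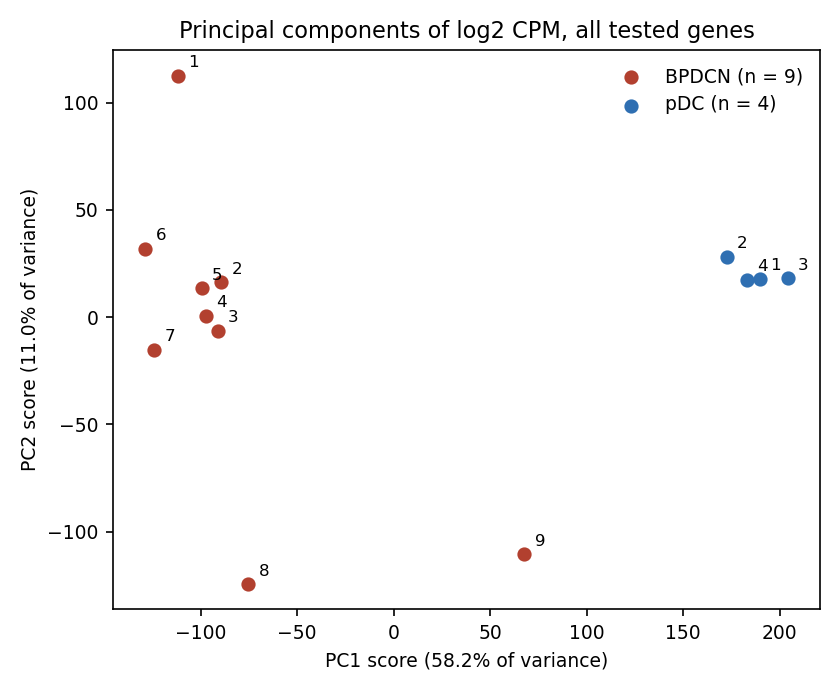
Scores of the 13 libraries on the first (58.2% of variance) and second (11%) principal components of log2 CPM, labelled by replicate number. The 4 pDC libraries (blue) lie at 172 to 204 on the first component, and BPDCN replicate 9 lies at 67.7, apart from the other tumours (red).

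The markers by which pathologists recognise BPDCN did not move in 1 direction. NCAM1, which encodes the adhesion molecule CD56, reached 244 ± 118 CPM (counts scaled to library size; SD, n = 9) in the tumours against 2.88 ± 0.273 (n = 4) in pDCs, a log2 fold change of 6.40 ± 0.575 (SE, edgeR adjusted p = 2.77e-06). TCL1A, a lymphoid co-activator of AKT, was higher by 2.19 ± 0.488 (adjusted p = 0.00244), although the groups overlapped. CD4 was lower by -1.72 ± 0.375 (adjusted p = 0.00212), at 489 ± 230 against 1615 ± 319 CPM. IL3RA, the interleukin-3 receptor chain CD123, was lower by -1.26 ± 0.50 (adjusted p = 0.0483). BPDCN replicate 1 had 791.3 CPM of IL3RA, against 55.3 to 190.9 in the other tumours and 451.6 to 555.6 in the pDCs. Without it the log2 fold change was -1.84 (edgeR adjusted p = 0.000214) and the groups did not overlap. The IL3RA call ended when any of the other 12 libraries was left out (adjusted p 0.0582 to 0.10, log2 fold change -1.33 to -1.13), and also with RLE size factors, upper-quartile scaling, a stricter low-count filter or a gene length trend removed (edgeR adjusted p = 0.0879, 0.124, 0.110 and 0.0630). CLEC4C, the pDC surface lectin BDCA-2, was lower by -3.59 ± 0.645 (adjusted p = 0.000598). TCF4, the transcription factor that specifies pDC identity, was lower by -1.59 ± 0.271 (adjusted p = 0.000411) and still stood at 499 ± 171 CPM in the tumours. With the tissue score as covariate, NCAM1 stayed called and the other 5 of these genes did not, at adjusted p 0.232 to 0.476. Their log2 fold changes in that fit were 1.06 for TCL1A, -1.39 for CD4, -1.87 for IL3RA, -2.13 for CLEC4C and -1.03 for TCF4.

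Over the 24 listed diagnostic antigens, 11 were higher, 6 lower and 7 not called (median log2 fold change 0.92, camera adjusted p = 0.490), with the same 11 and 6 adjusted over the list alone. The largest rises in that list were DNTT, the terminal transferase of immature lymphocytes (10.21), and CD34, a marker of progenitors and vessels (7.5). The DNTT value was 9.08 without BPDCN replicate 3 and 11.07 without pDC replicate 3, with only 10 counts over the pDC group. Neither stayed called with the tissue score as covariate, where DNTT stood at 7.81 and CD34 at 1.52 (edgeR adjusted p = 0.0973 and 0.288). CD68, a lysosomal glycoprotein, was lower by -1.89. CD68 kept its call with the tissue score, though not when BPDCN replicate 9 was also left out (-2.33, edgeR adjusted p = 0.142).

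Lists of the normal pDC programme were called lower in the tumours. Of 41 surface and secreted markers, 25 were lower, 0 higher and 16 not called, and 25 were lower adjusted over the list alone. Their median log2 fold change was -1.61, and camera with a preset correlation gave adjusted p = 2.60e-12 (adjusted p = 0.188 with an estimated correlation). Granzyme B, GZMB, which pDCs secrete, fell by 4.99 on the log2 scale from 1537 ± 235 to 48.5 ± 55.6 CPM. ASIP, a secreted signalling protein, fell by 4.6. Of 23 transcription factors and adaptors, 14 were lower and 2 higher, the same numbers as adjusted over the list alone, with a median of -0.86 (camera adjusted p = 3.79e-05; adjusted p = 0.268 with an estimated correlation). IRF4, an interferon regulatory factor of lymphoid and dendritic cells, fell by 4.87 to 47.3 ± 26.5 CPM, and the adaptor SLA2 fell by 3.20. The inhibitor of DNA binding ID3 rose by 3.70 and TCL1A by 2.19. SLA2 (-2.50) and ID3 (2.64) lost their calls with the tissue score as covariate (edgeR adjusted p = 0.163 and 0.111), while GZMB, ASIP and IRF4 kept theirs. Leaving out BPDCN replicate 9 in that fit ended the calls of GZMB (-4.73, edgeR adjusted p = 0.238) and IRF4 (-3.67, adjusted p = 0.0580).

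Of 25 genes for Toll-like receptor signalling and interferon induction, 11 were lower and 0 higher over all genes, and 11 were lower and 1 higher adjusted over the list alone (median -0.77, camera adjusted p = 0.00526; adjusted p = 0.376 with an estimated correlation). TLR9, the receptor for unmethylated DNA, fell by 3.06 and TLR6 by 2.54. Neither was called with the tissue score as covariate (-3.41 and -1.48, edgeR adjusted p = 0.0533 and 0.187), and TLR6 was called in that fit without BPDCN replicate 9 (-3.22, adjusted p = 0.0221). Interferon-stimulated genes went both ways: 13 of 41 were higher and 3 lower (12 and 3 adjusted over the list alone), with a median of 0.67 and no call for the list (camera adjusted p = 0.221). CXCL9, a chemokine that draws T cells, rose by 8.71 and IFI27 by 7.51, whereas IFIT2 fell by 2.45 and SP110 by 1.21. CXCL9 stood at 8.02 without BPDCN replicate 7. In the fit with the tissue score the list median was -0.29, IFI27 and SP110 lost their calls (1.78 and -1.06, edgeR adjusted p = 0.591 and 0.281), IFIT2 kept its call (-3.61) and CXCL9 did too (6.93, adjusted p = 0.00668), though not when BPDCN replicate 9 was also left out (6.26, adjusted p = 0.0711). Leaving out pDC replicate 4 brought this list past the threshold (median 1.08, camera adjusted p = 0.0397). All 3 pDC lists kept their call with the tissue score as covariate, with medians of -1.90, -0.84 and -0.80.

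Cell division genes rose together. Of 45 proliferation genes, 44 were higher and 0 lower in BPDCN, also adjusted over the list alone, with a median log2 fold change of 3.92 (camera adjusted p = 4.73e-38; adjusted p = 0.115 with an estimated correlation). BIRC5, which encodes survivin, rose by 8.56 and the mitotic kinase AURKB by 8.01. The value of BIRC5 was 9.21 without pDC replicate 4. The mean of the list was 5.44 ± 0.433 log2 CPM in the tumours (n = 9, range 4.84 to 6.28) and 1.33 ± 0.222 in the pDCs (n = 4, range 1.18 to 1.66). BPDCN replicate 9, which had the lowest tissue score of the tumours (-0.50, against -2.18 to -1.34 in the pDCs), stood at 5.17. MYC, a growth-promoting transcription factor, did not pass the test at 1.07 ± 0.875 (edgeR adjusted p = 0.324), with 28.6 ± 39.1 CPM in tumours and 13.6 ± 13.3 in pDCs.

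Regulators of apoptosis changed in opposite directions. BCL2, which holds back mitochondrial cell death, rose by 3.91 ± 0.481 (edgeR adjusted p = 3.63e-05), from 12.9 ± 7.77 CPM in pDCs to 195 ± 80.5 in tumours, and kept its call with the tissue score as covariate (4.6, adjusted p = 0.000275). MCL1, a related survival protein, fell by 2.22 from 1537 ± 495 to 329 ± 109 CPM, and BCL2L13 fell by 1.20. MCL1 (-1.83) and BCL2L13 (-1.04) lost their calls in that covariate fit (edgeR adjusted p = 0.0658 and 0.114). BCL2L14 had no counts in any pDC library and was at least 171-fold higher in BPDCN against a floor of 3 counts over the pDC group, or 114-fold without BPDCN replicate 8. In the whole BCL2 family, 9 of 19 genes were higher and 2 lower, also adjusted over the list alone, with a median of 0.996 and no call for the list (camera adjusted p = 0.402).

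Among 24 tumour suppressor and lymphoid genes known to be deleted or mutated in this disease, 5 were higher and 5 lower, also adjusted over the list alone (median -0.21, mean 0.47, camera adjusted p = 0.498). The cell cycle inhibitor CDKN2A rose by 6.76 and CDKN2B by 4.06, or 3.47 without BPDCN replicate 7. ZEB2 fell by 1.27, and the retinoblastoma gene RB1 fell by 1.19 (adjusted p = 0.0322). That RB1 call ended when any of 6 libraries was left out, namely BPDCN replicates 2 and 6 and each of the 4 pDC replicates, at adjusted p 0.0524 to 0.0743. Library size alone and upper-quartile scaling also ended the RB1 call (edgeR adjusted p = 0.0964 and 0.0501). The tissue score as covariate ended the calls of RB1 (-0.30, edgeR adjusted p = 0.851), CDKN2B (2.13, adjusted p = 0.324) and ZEB2 (-0.59, adjusted p = 0.483). CDKN2A stayed called there (5.26) but not without BPDCN replicate 9 (2.72, edgeR adjusted p = 0.506).

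Splicing factors were lower in 10 of 30 cases and higher in 2, also adjusted over the list alone (median -0.54, camera adjusted p = 0.0156; adjusted p = 0.487 with an estimated correlation). SRSF6 fell by 1.47 and PRPF40B by 1.34, whereas SNRPD1 rose by 1.18. SF3A3 was at 0.58, and its call (adjusted p = 0.0432) ended without BPDCN replicates 2 or 3 or any of the 4 pDC replicates (adjusted p 0.0512 to 0.116), without a low-count filter (0.0791) and with a gene length trend removed (0.0767). The call for this list was lost with the tissue score as covariate, at a median of -0.41 (camera adjusted p = 0.166). All 4 of these genes lost their calls there, with SRSF6 at -0.52, PRPF40B at -2.01, SNRPD1 at 1.33 and SF3A3 at 0.77 (edgeR adjusted p 0.0637 to 0.616), and only SNRPD1 was called in that fit without BPDCN replicate 9 (2.88, adjusted p = 0.0190).

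Of 11 lists of chromatin regulators, the theme of the study's title, camera called 5 lower and 0 higher. Histone lysine demethylases were lower in 12 of 24 cases and higher in 1, or 14 and 1 adjusted over the list alone, with a median log2 fold change of -0.90 (camera adjusted p = 0.000305; adjusted p = 0.487 with an estimated correlation). KDM7A fell by 2.30 and KDM2A by 1.70, while HR, a demethylase of the hair follicle, rose by 8.62 with overlapping groups, or 7.12 without BPDCN replicate 7 and 9.74 without pDC replicate 1. HR had only 5 counts over the pDC group, so the size of its fold is uncertain. Histone acetyltransferase genes were lower in 13 of 27 cases and higher in 2, also adjusted over the list alone, at a median of -0.76 (camera adjusted p = 0.000148; adjusted p = 0.487 with an estimated correlation). EP300, a general co-activator, fell by 1.86 and HAT1 rose by 1.40. NCOA2 was at -1.93, or -2.53 without BPDCN replicate 9, and lost its call without pDC replicate 1 or 3 (adjusted p = 0.0591 and 0.0513). TADA3 was at 0.78 and lost its call in 5 cases, without BPDCN replicates 3 or 4 or pDC replicates 1, 3 or 4 (adjusted p 0.0517 to 0.0905), and without a low-count filter (adjusted p = 0.0569). HR stood at -2.89 and TADA3 at -0.11 with the tissue score as covariate, neither of them called. Without BPDCN replicate 9 that fit gave 1.34 for TADA3, also not called (edgeR adjusted p = 0.190). KDM7A, KDM2A, EP300, HAT1 and NCOA2 also lost their calls with the tissue score (-1.40, -1.21, -1.43, 1.84 and -0.99, edgeR adjusted p 0.0682 to 0.597). Of these, all but KDM7A were called without BPDCN replicate 9 (-2.26, -2.82, 2.63 and -5.89, edgeR adjusted p 0.0120 to 0.0431).

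Histone lysine methyltransferases were lower in 16 of 39 cases and higher in 5, also adjusted over the list alone (median -0.38, camera adjusted p = 0.0116; adjusted p = 0.562 with an estimated correlation). Without BPDCN replicate 9 the median of this list was -0.59. KMT2D and KMT2B, which methylate lysine 4 of histone H3, fell by 2.16 and 1.92, and SETMAR and SUV39H1 rose by 1.70 and 1.45. CHD, ISWI and INO80 remodellers were lower in 13 of 29 cases and higher in 1, also adjusted over the list alone (median -0.59, camera adjusted p = 0.00526; adjusted p = 0.487 with an estimated correlation). BAZ2A fell by 2.18 and CHD2 by 2.09, and RUVBL2 rose by 1.73. The list of bromodomain and cohesin proteins also held Mediator subunits, CDK genes and CCNT1. Of its 20 tested genes, 7 were lower and 0 higher, or 4 and 0 adjusted over the list alone (median -0.54, camera adjusted p = 0.0139, or 0.645 with an estimated correlation). BRD2 fell by 1.32 and CCNT1 by 1.30. With the tissue score as covariate, demethylases and acetyltransferases kept their call (adjusted p = 0.0262 and 0.0329), and the other 3 of these 5 lists did not (adjusted p = 0.328, 0.246 and 0.665). That loss depended on BPDCN replicate 9 for the methyltransferases and the remodellers, which were called in the same fit without it (medians -1.09 and -0.81, camera adjusted p = 0.0113 for both). Bromodomain and cohesin proteins were not (median -0.33, camera adjusted p = 0.240). None of the 9 genes named from these 3 lists was called with the tissue score (edgeR adjusted p 0.0530 to 0.910). There KMT2D stood at -1.97, KMT2B at -2.38, SETMAR at 1.39, SUV39H1 at 0.67, BAZ2A at -1.72, CHD2 at -1.46, RUVBL2 at 0.23, BRD2 at -1.27 and CCNT1 at -0.44. KMT2D, KMT2B, BAZ2A and CHD2 were called in that fit without BPDCN replicate 9 (-4.76, -4.57, -4.11 and -3.38).

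The remaining chromatin groups were not called as lists. In Polycomb repressive complex PRC2 and its partners, 1 of 14 genes was higher and 3 lower (1 and 2 adjusted over the list alone; median -0.19, camera adjusted p = 0.361). The catalytic subunit EZH2 rose by 1.34 ± 0.217 (edgeR adjusted p = 0.000284), from 18.9 ± 1.86 to 48.0 ± 8.70 CPM, and its paralogue EZH1 fell by 1.81. ASXL2 fell by 1.92, with -2.56 without BPDCN replicate 9, while ASXL1 did not pass the test (-0.05 ± 0.207, adjusted p = 0.854). In PRC1, 5 of 24 genes were higher and 8 lower, also adjusted over the list alone (median -0.26, camera adjusted p = 0.0843). PHC3 fell by 2.10 and CBX2 rose by 1.59. PCGF2 was at 3.08, a call lost without pDC replicate 1, 3 or 4 (adjusted p 0.0538 to 0.0647), and it stood at -2.39 with the tissue score as covariate. Without a low-count filter the PRC1 list passed the threshold (adjusted p = 0.0197). EZH2 kept its call with the tissue score as covariate (1.63, edgeR adjusted p = 0.00968). EZH1 (-1.35), ASXL2 (-0.78), PHC3 (-0.74) and CBX2 (0.37) did not (edgeR adjusted p 0.131 to 0.787), although EZH1 and ASXL2 were called when BPDCN replicate 9 was also left out (-3.04 and -5.62).

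In DNA methylation, 4 of 23 genes were higher and 5 lower, or 4 and 3 adjusted over the list alone (median 0.01, with camera pointing lower at adjusted p = 0.519). TET2, a DNA demethylase, fell by 1.94 ± 0.259 (edgeR adjusted p = 6.71e-05), from 176 ± 15.9 to 45.9 ± 16.4 CPM, and TET3 fell by 2.20. The methyltransferase DNMT3B rose by 2.41. TET2, TET3 and DNMT3B lost their calls with the tissue score as covariate (-1.23, -1.78 and 2.10, edgeR adjusted p = 0.114, 0.0835 and 0.0531), and TET3 alone of these was called in that fit without BPDCN replicate 9 (-3.60, adjusted p = 0.00697). DNMT1 did not pass the test (-0.25 ± 0.383, adjusted p = 0.606). Histone deacetylases and corepressors had 3 of 28 genes higher and 7 lower, also adjusted over the list alone (median -0.25, camera adjusted p = 0.213). HDAC11 rose by 2.29 and RCOR2 by 2.0, and SIN3B fell by 1.30. None of these 3 genes was called with the tissue score as covariate (0.35, 0.27 and -1.75, edgeR adjusted p = 0.805, 0.912 and 0.0732), though SIN3B was when BPDCN replicate 9 was also left out (-3.33, adjusted p = 0.0171). In SWI/SNF complexes, 5 of 30 genes were higher and 6 lower, or 4 and 6 adjusted over the list alone. Their median was -0.16 and their mean 0.16 (camera adjusted p = 0.221). BCL11B, a T cell transcription factor, rose by 3.61 and BCL7C by 3.08 (2.22 without BPDCN replicate 1), whereas BCL11A and ARID1B fell by 1.75 and 1.28. BCL7C (0.44) and ARID1B (-1.20) lost their calls with the tissue score (edgeR adjusted p = 0.92 and 0.142), and BCL11B (3.87) and BCL11A (-1.78) only when BPDCN replicate 9 was left out as well (adjusted p = 0.162 and 0.129). Of 10 protein arginine methyltransferases, 1 was higher and 1 lower, and 0 adjusted over the list alone (median 0.07, mean 0.13, with camera pointing lower at adjusted p = 0.919).

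**Figure D3:**
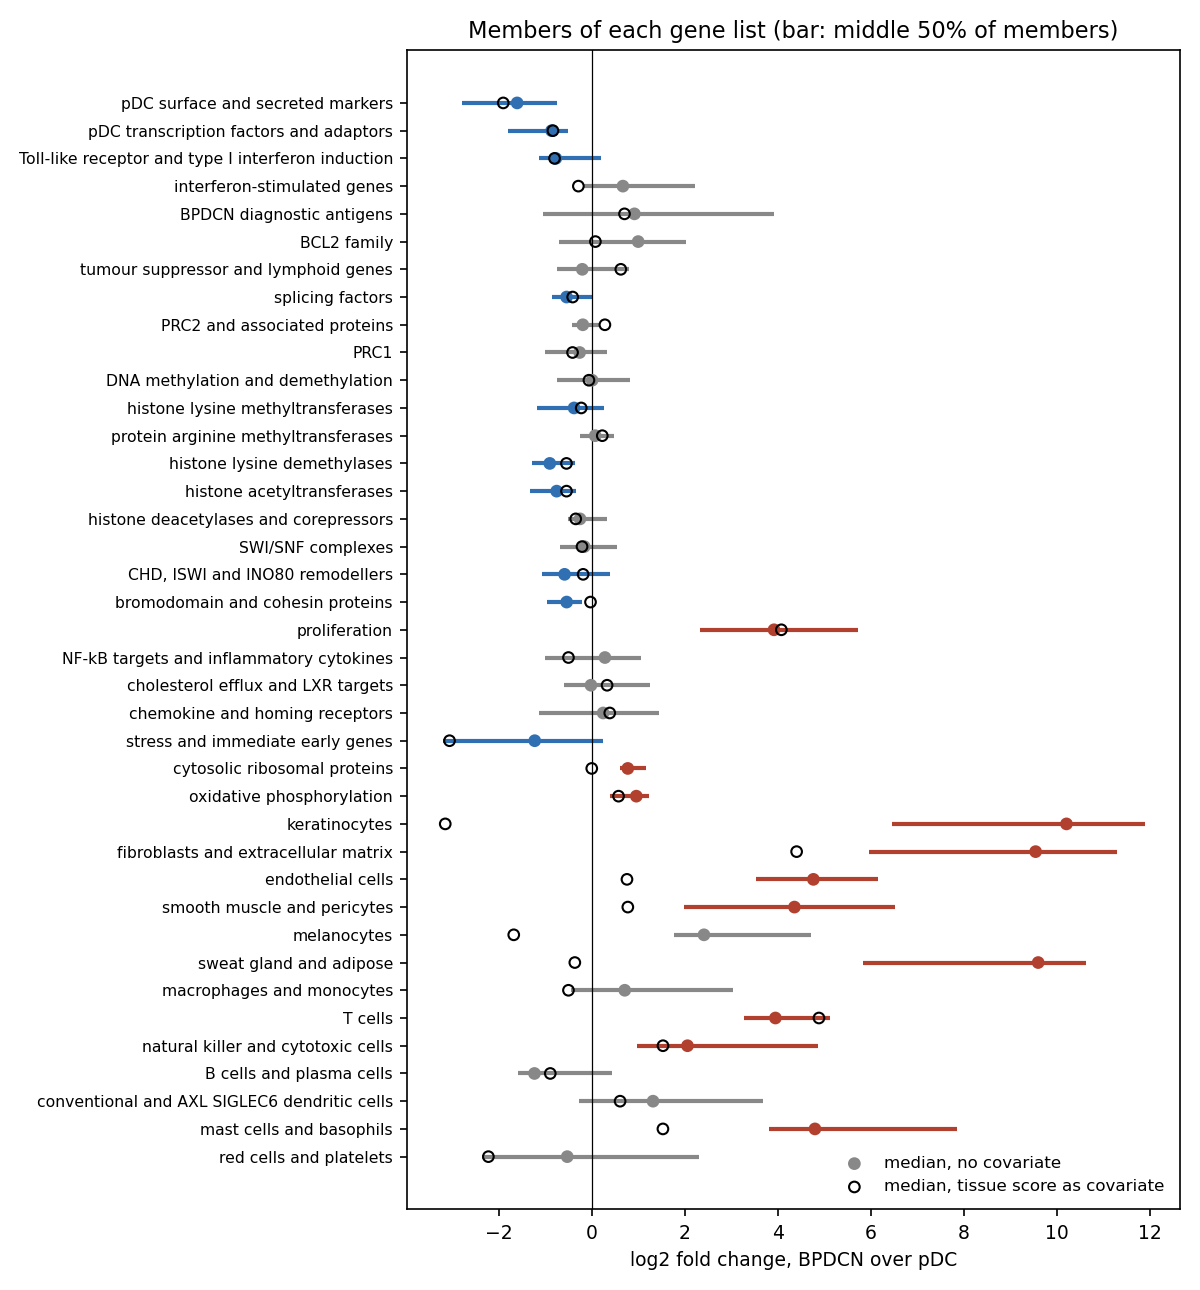
For each of the 39 gene lists, the filled point is the median log2 fold change of BPDCN over pDC and the bar spans the middle 50% of its members, red or blue where camera called the list higher or lower and grey otherwise; open points are medians with the tissue score as covariate. The proliferation median was 3.92 and 4.07 in the 2 fits, and the keratinocyte median was 10.2 and -3.15.

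Other cell states gave further differences. Stress and immediate early genes, which respond within minutes to stimulation or handling, were lower in 14 of 30 cases and higher in 3, or 15 and 4 adjusted over the list alone. Their median was -1.23 (camera adjusted p = 9.33e-05; adjusted p = 0.487 with an estimated correlation). Without pDC replicate 2 the median was -0.76. FOSB fell by 6.72 from 792 ± 654 to 7.49 ± 5.74 CPM and FOS by 3.85 (FOSB stood at -6.09 without pDC replicate 4), whereas the heat shock genes HSPA1B and HSPA1A rose by 3.62 and 2.74. These last genes are near-identical copies whose reads the counting could have split. HSPA1A was not called with the tissue score as covariate (1.05, edgeR adjusted p = 0.417). FOSB, FOS and HSPA1B were, but not without BPDCN replicate 9 (-7.42, -4.29 and 2.52, edgeR adjusted p 0.0998 to 0.182). Cytosolic ribosomal proteins had 7 of 53 genes higher and 0 lower, and 0 adjusted over the list alone (median 0.77, camera adjusted p = 0.0310; adjusted p = 0.774 with an estimated correlation). That ribosomal call ended without BPDCN replicate 1, 5 or 8 or pDC replicate 1 or 3 (adjusted p = 0.0684, 0.0514, 0.0548, 0.0614 and 0.0510), and with DESeq2 (adjusted p = 0.112). The ribosomal median was -0.0015 with the tissue score as covariate, and 1.47 when BPDCN replicate 9 was also left out (camera adjusted p = 0.00766). Oxidative phosphorylation genes were higher in 18 of 39 cases and lower in 1, or 21 and 1 adjusted over the list alone (median 0.96, camera adjusted p = 0.0288; adjusted p = 0.676 with an estimated correlation). UQCRQ and NDUFA2 rose by 2.05 and 1.6. The oxidative phosphorylation call ended without pDC replicate 1 (adjusted p = 0.05004), with DESeq2 (adjusted p = 0.123) and with the tissue score as covariate (adjusted p = 0.369), though not in that fit without BPDCN replicate 9 (median 2.03, adjusted p = 8.27e-06). UQCRQ and NDUFA2 were not called with the tissue score (1.25 and 1.14, edgeR adjusted p = 0.537 and 0.566), and NDUFA2 was without BPDCN replicate 9 (3.93, adjusted p = 0.0297).

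NF-kB targets and cytokines went both ways, with 5 of 28 genes higher and 6 lower, also adjusted over the list alone. Their median was 0.28 and their mean -0.07 (camera pointing lower, adjusted p = 0.417). The chemokines CCL2 and CCL5 rose by 6.17 and 5.27, and CXCL8 and PTGS2 fell by 7.23 and 4.03. CCL2 stood at 7.40 without pDC replicate 2 and CXCL8 at -6.31 without pDC replicate 4. These 4 genes kept their calls with the tissue score, but CCL5 (4.94) and PTGS2 (-5.43) did not without BPDCN replicate 9 (edgeR adjusted p = 0.112 and 0.0567). Cholesterol efflux genes and liver X receptor targets were higher in 6 of 18 cases and lower in 3, also adjusted over the list alone (median -0.02, mean 1.13, camera adjusted p = 0.612). The apolipoprotein genes APOC1 and APOE rose by 8.66 and 7.38 and SREBF2 fell by 1.48. APOE was not called with the tissue score (3.43, edgeR adjusted p = 0.0570) but was when BPDCN replicate 9 was also left out (5.28, adjusted p = 0.0335), and SREBF2 was not called in that last fit (-1.61, adjusted p = 0.144). MYLIP was at -0.99, a call that 7 of the single-library omissions ended (adjusted p 0.0562 to 0.142), as did upper-quartile scaling, library size alone and the tissue score (adjusted p = 0.0668, 0.129 and 0.634). Chemokine and homing receptors had 6 of 22 genes higher and 5 lower, or 7 and 6 adjusted over the list alone (median 0.24, camera adjusted p = 0.999).

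Markers of other skin cells were higher in the tumour libraries. The tissue score, a mean over keratinocyte, fibroblast and endothelial markers, was 3.47 ± 1.93 log2 CPM in BPDCN (n = 9, range -0.50 to 6.33) and -1.74 ± 0.340 in pDCs (n = 4). The difference of 5.21 had p = 0.0014 in an exact 2-sided permutation test, the smallest that the 715 splits can give. Keratinocyte markers were higher in 30 of 35 cases and lower in 0, also adjusted over the list alone (camera adjusted p = 0.00128; adjusted p = 0.676 with an estimated correlation). Their fitted median was 10.2 (8.31 without BPDCN replicate 7), or 8.98 with the 13 members at 0 in all pDC libraries set to their bound. The mean of the keratinocyte list was -2.48 and -2.81 log2 CPM in BPDCN replicates 8 and 9, against -2.63 to -2.20 in the pDCs, and -0.40 to 7.07 in the other tumours. KRT14 and KRT17 were at least 21000-fold and 2540-fold higher against a floor of 3 counts over the pDC group, although each had 0 counts in 1 tumour. BPDCN replicate 7 held 2170 and 259.5 CPM of them, and without it these bounds were 6010-fold and 744-fold. Neither gene was called with the tissue score (edgeR adjusted p = 0.760 and 0.843). All 30 fibroblast and matrix genes were higher, also adjusted over the list alone, with a median of 9.54 that did not move with 4 members at their bound (camera adjusted p = 7.61e-22; adjusted p = 0.321 with an estimated correlation).

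Among the called genes whose groups did not overlap, the largest fitted increases under the rule for named genes were those of DCN, CXCL14, DPT, CDH11 and NNMT, which had no counts in any pDC library. Against the same floor they were at least 13900, 10000, 3520, 3370 and 3000 times higher in BPDCN. These 5 genes, with CCL21, SFRP2 and ADH1B (at least 2960, 2800 and 1830 times higher), were also those with the largest increases under the rule that stayed called with the tissue score as covariate. DCN, DPT and SFRP2 belong to the fibroblast list that helps build the score, so they are adjusted for themselves. That list kept a median of 4.40 in the same fit, so keeping a call there does not free a gene of skin signal. The bound for CCL21 was 1760-fold without BPDCN replicate 8 and that for ADH1B 1240-fold without BPDCN replicate 5. The same rule left out genes of a mean log2 CPM below 1 over all libraries, LRCOL1 (-8.26), C5orf64 (-7.27) and CXCL8 (-7.23) among them. In pDCs alone LRCOL1 and C5orf64 averaged 5.58 and 5.05 log2 CPM. Among the genes kept by the rule, the largest decreases that separated the groups were FOSB (-6.72), the phosphatase DUSP5 (-6.38), COL26A1 (-6.32), NLRP7 (-5.56), CDHR5 (-5.44), C10orf105 (-5.11), the flippase ATP10A (-5.07) and the transcription factor DACH1 (-5.04). All 8 of these stayed called with the tissue score as covariate (adjusted p 3.33e-05 to 0.0497), but without BPDCN replicate 9 that fit no longer called FOSB, COL26A1 and C10orf105, at -7.42, -6.43 and -3.31 (edgeR adjusted p = 0.0998, 0.135 and 0.0612). The fit without covariate gave FOSB -6.09 without pDC replicate 4, COL26A1 -7.63 without BPDCN replicate 4, NLRP7 -6.24 without BPDCN replicate 5 and CXCL8 -6.31 without pDC replicate 4.

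Endothelial genes were higher in 18 of 20 cases and lower in 1, or 19 and 1 adjusted over the list alone (median 4.76, camera adjusted p = 1.66e-06; adjusted p = 0.487 with an estimated correlation). ACKR1 and ECSCR rose by 8.94 and 7.98, with only 10 and 4 counts over the pDC group. Those of ECSCR all lay in pDC replicate 2. Its fitted value without that library (10.69) therefore rests on 0 pDC counts and is no measured fold. ECSCR kept its call with the tissue score (4.43) and ACKR1 did not (3.75, edgeR adjusted p = 0.124), unless BPDCN replicate 9 was also left out (6.47, adjusted p = 0.0181). MMRN1 was at -1.72, a call that 9 of the single-library omissions ended (adjusted p 0.0516 to 0.0999), as did library size alone and the tissue score (adjusted p = 0.0785 and 0.652). Smooth muscle and pericyte genes were higher in 12 of 14 cases, also adjusted over the list alone (median 4.35, camera adjusted p = 0.000219; adjusted p = 0.487 with an estimated correlation), with CSPG4 up by 8.40 and DES by 7.11 (7.77 without pDC replicate 1). Melanocyte genes were higher in 5 of 9 cases, also adjusted over the list alone (median 2.41, camera adjusted p = 0.213), and their median was 1.51 or 1.41 without BPDCN replicate 5 or 7 and 3.02 or 3.35 without pDC replicate 1 or 2. OCA2 rose by 7.42, and TYRP1, with no counts in pDCs or in 2 tumours, was at least 85.6-fold higher, or 38.2-fold without BPDCN replicate 7. Sweat gland and adipose genes were higher in 13 of 15 cases, or 14 adjusted over the list alone (median 9.59, 8.19 without BPDCN replicate 5, or 7.97 with 8 members at their bound; camera adjusted p = 0.0324; adjusted p = 0.676 with an estimated correlation). DCD and MUCL1, at 0 in 3 and 2 of the tumours, were at least 5070-fold and 741-fold higher. BPDCN replicate 5 held 492.9 and 75.7 CPM of them, and without it these bounds were 1690-fold and 217-fold. The sweat gland and adipose call ended without BPDCN replicate 1 (adjusted p = 0.0610), under upper-quartile scaling (0.0716), with library size alone (0.0566), with a stricter low-count filter (0.0973) and with BPDCN replicates 1 and 9 left out (0.0765). With the tissue score as covariate the keratinocyte list was called lower (median -3.15, camera adjusted p = 0.00144), and the medians were -1.68 for melanocytes and -0.37 for sweat gland and adipose genes. In that fit the endothelial, smooth muscle, and sweat gland and adipose lists were not called (adjusted p = 0.463, 0.877 and 0.877), while fibroblast genes stayed higher (median 4.40, adjusted p = 7.82e-17). Keratinocyte, fibroblast and endothelial genes make up the score, so these lists are adjusted for themselves and their results there are no test of the tissue. Without BPDCN replicate 9 that fit called the endothelial list higher (median 2.41, camera adjusted p = 0.0194). TYRP1 and MUCL1 stood at -1.68 and -1.22 with the tissue score, and they, DES (1.38) and DCD (3.08) were not called (edgeR adjusted p 0.658 to 0.905). CSPG4 and OCA2 were, but OCA2 was not when BPDCN replicate 9 was also left out (4.06, edgeR adjusted p = 0.254).

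Marker lists of T cells, natural killer cells and mast cells were called higher. All 20 T cell genes were higher in BPDCN, also adjusted over the list alone, with a median of 3.95 (camera adjusted p = 3.37e-06; adjusted p = 0.487 with an estimated correlation), and SH2D1A and CD3D rose by 6.71 and 6.66. Natural killer and cytotoxic genes were higher in 8 of 15 cases and lower in 1, also adjusted over the list alone (median 2.06, camera adjusted p = 0.00882; adjusted p = 0.551 with an estimated correlation). GZMK and EOMES rose by 7.70 and 7.07. KLRF1 was at -2.22 and lost its call without pDC replicate 2 or 4 (adjusted p = 0.116 and 0.0567) and with the tissue score (-3.87, adjusted p = 0.0695), though not in that fit without BPDCN replicate 9 (-5.91, adjusted p = 0.0392). Mast cell and basophil genes were higher in 9 of 11 cases and lower in 1, or 10 and 1 adjusted over the list alone (median 4.80, also with 1 member at its bound, and 5.54 without pDC replicate 4; camera adjusted p = 0.0237; adjusted p = 0.582 with an estimated correlation). TPSB2 was at least 1080-fold higher. TPSAB1, a near-identical paralogue, was called higher with 2 counts over the pDC group, and SLC18A2 fell by 2.62. These 3 mast cell genes were not called with the tissue score (4.04, 3.27 and -1.68, edgeR adjusted p 0.328 to 0.521). The T cell and natural killer lists stayed called with the tissue score as covariate (adjusted p = 1.43e-14 and 0.00314) and the mast cell list did not (adjusted p = 0.839). Without BPDCN replicate 9 that fit kept the T cell list (adjusted p = 4.73e-06) and lost the natural killer list (median 2.57, camera adjusted p = 0.166).

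Macrophage and monocyte genes were higher in 8 of 20 cases and lower in 3, also adjusted over the list alone (median 0.71, camera adjusted p = 0.520). The complement genes C1QB and C1QA rose by 5.17 and 5.03, and S100A12 and FCN1 fell by 4.19 and 3.36. C1QB and C1QA stood at 6.40 and 5.87 without pDC replicate 4, and FCN1 at -4.44 without BPDCN replicate 6. None of these 4 was called with the tissue score as covariate (2.36, 2.22, -3.09 and -6.22, edgeR adjusted p 0.105 to 0.319). Genes of conventional and AXL SIGLEC6 dendritic cells were higher in 8 of 21 cases and lower in 1, also adjusted over the list alone (median 1.31, or 0.61 without BPDCN replicate 8; camera adjusted p = 0.285). CD1E rose by 8.93, or 5.12 without BPDCN replicate 8, which had 1292 CPM against 0.750 to 32.9 in the other tumours, and 9.87 without pDC replicate 4. CADM1 rose by 6.98 and DAB2 fell by 1.38. DAB2 was not called with the tissue score (-2.23, edgeR adjusted p = 0.0731), and CD1E and CADM1 were. B cell and plasma cell genes were higher in 2 of 15 cases and lower in 3, also adjusted over the list alone (median -1.23, camera adjusted p = 0.156). SDC1 and FCRLA rose by 7.13 and 1.99, and FCRL1 fell by 4.03. BPDCN replicate 7 had 170.2 CPM of SDC1, and its value was 5.18 without that library and 8.46 without pDC replicate 2. With the tissue score as covariate SDC1 stood at -0.89, FCRLA at 2.41, FCRL1 at -2.94 and PAX5 at -2.81, none of them called (edgeR adjusted p 0.0909 to 0.635). PAX5 was at -2.71 and lost its call without pDC replicate 1 or 2 (adjusted p = 0.0501 and 0.0663). The B cell list passed the threshold without pDC replicate 3 (median -1.56, adjusted p = 0.0278) and without a low-count filter (adjusted p = 0.0474). Red cell and platelet genes were higher in 1 of 10 cases and lower in 4, also adjusted over the list alone (median -0.53, or 0.58 without pDC replicate 2; camera adjusted p = 0.298).

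**Figure D4:**
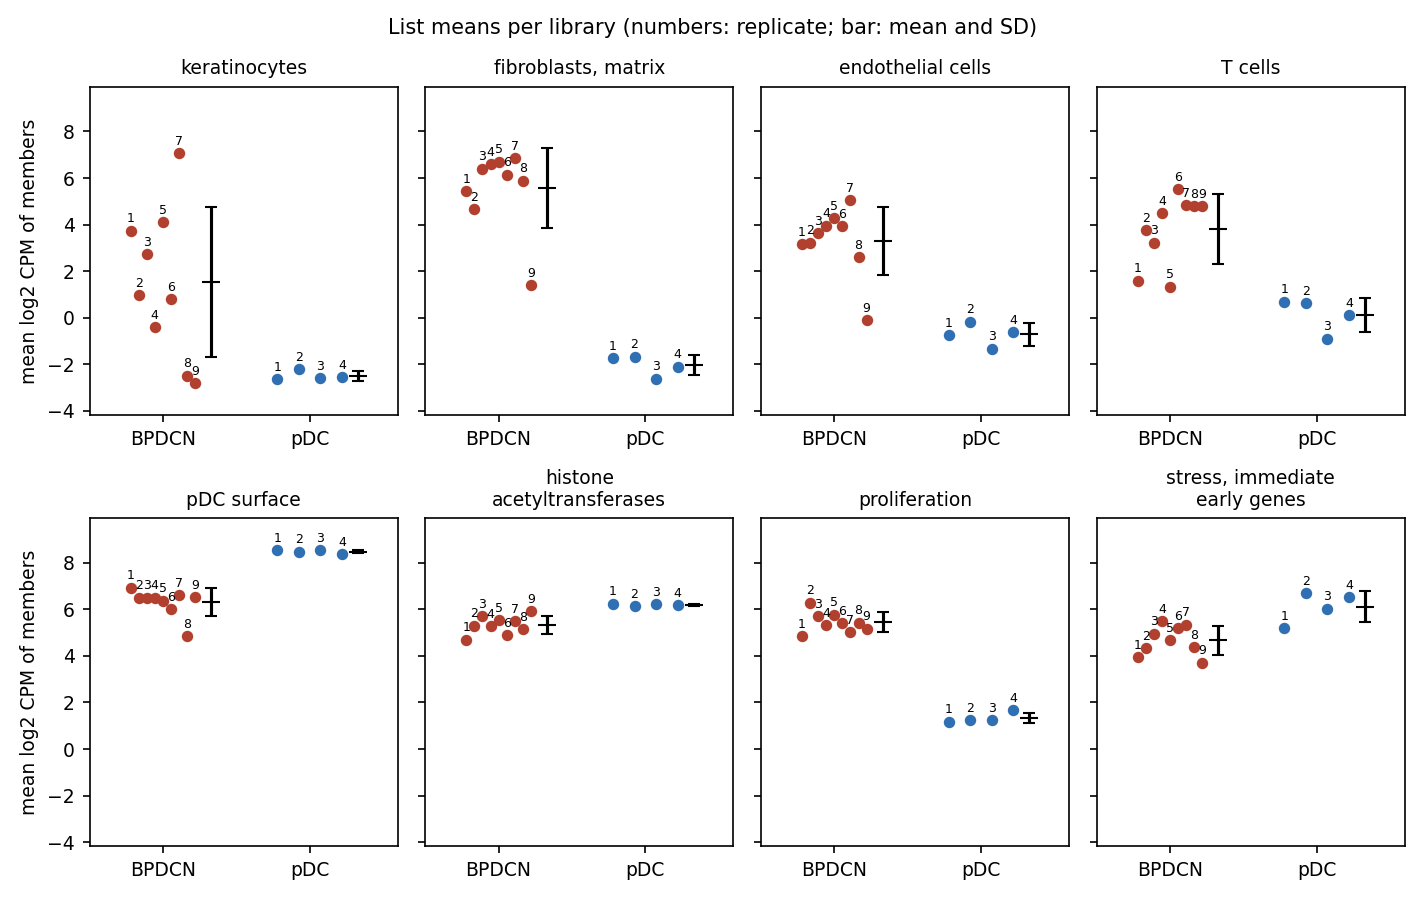
Mean log2 CPM of the members of 8 gene lists in each library, labelled by replicate number, with the mean and SD of each group as black bars. The proliferation list lay at 4.84 to 6.28 in the tumours and 1.18 to 1.66 in the pDCs, and BPDCN replicate 9 had a fibroblast mean of 1.40 against 4.66 to 6.85 in the other tumours.

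In total camera called 21 of the 39 lists, 11 higher and 10 lower, and 0 with an estimated correlation. The list means of the groups overlapped for 6 of these 21, namely histone lysine methyltransferases, bromodomain and cohesin proteins, stress and immediate early genes, ribosomal proteins, oxidative phosphorylation and keratinocytes. There were 11 called lists with the tissue score as covariate, 10 of them in the direction called without it, while keratinocytes were called lower instead of higher. The keratinocyte and fibroblast lists among these are part of the score and were adjusted for themselves. Of the 143 genes named by the rule for named genes, 55 kept their side of the threshold in that fit, 80 lost their call and 8 called genes changed sign.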

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

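The comparisons of single lists, and of the chromatin lists pooled, with other splits of the libraries, removal of the gene length trend, the gap over all 11 chromatin lists with its interval, and the covariate fit without BPDCN replicate 9, were chosen only after the data or results were seen; the other tests were set before.

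The counts of 5131 higher and 3294 lower genes exceeded those of every other split drawn, of which the highest gave 2596 and 991. A chance division of these libraries can be excluded at 1 of 100 splits for each. The splits treat libraries as independent, and the labels give no donors, so chance differences between donors are not excluded. For the number of called lists chance cannot be excluded, since 21 of 100 splits called at least as many as the real 21 and the highest called 27. Of the 21 called lists, 19 had a gap to all genes that fewer than 5 splits matched, but only 3 (pDC surface markers, proliferation and fibroblasts) had a camera p that fewer than 5 matched. Of all 39 lists 25 had such a gap, uncalled ones among them, so the gap alone sets no list apart. The keratinocyte gap of 9.99 was close to the highest of another split (9.92).

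Of the 11 chromatin lists 5 were called lower in BPDCN, and none of these with an estimated correlation (camera adjusted p 0.487 to 0.645). The median log2 fold change of all 263 members lay -0.59 from that of all genes (95% bootstrap interval over members -0.73 to -0.49). No other split drawn gave a gap as large (at most 0.50, 1 of 100 with the real one), without adjustment for the choice of test. The camera p of the 5 lists was matched by 8 to 42 of 100 splits, so chance cannot be excluded for it. Over all genes the trend on gene length was slight before its removal, at 0.125 log2 fold change per 10-fold length (Spearman correlation -0.10), and 0.0416 after. The 139 members of the 5 called lists were chosen by their call, so their gap of -0.87 is no test that they were lower. A gene length trend as the whole cause of that gap is argued against by -0.80 (-0.96 to -0.61) after removal of the trend (-0.54 over all 11 lists). With the skin marker score as covariate the gap of these members was -0.36 (-0.56 to -0.20), or -0.28 (-0.43 to -0.16) over all 11 lists, and 2 of the 5 lists stayed called. Without BPDCN replicate 9 the gap in that fit was -1.30 (-1.53 to -1.08), or -0.95 over all 11 lists, and 4 of the 5 lists stayed called. Its size therefore rests on this library. The scores did not overlap between the groups (-2.18 to -1.34 in pDCs, -0.50 to 6.33 in tumours), and the intervals leave out the spread between libraries. The fit thus cannot decide whether what the score measures is the whole cause. Tumour against normal cell, skin against blood beyond these markers, and handling of biopsies against isolated cells were not tested and may each contribute.

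Of 45 proliferation genes, 44 were higher in BPDCN. The list was called higher with the preset correlation but not with an estimated one (camera adjusted p = 0.115). With the tissue score as covariate the list median was 4.07 (5.27 without BPDCN replicate 9), in a fit where the scores of the groups did not overlap. Across tumours with scores of -0.50 to 6.33 the list mean was 4.84 to 6.28 log2 CPM, against 1.18 to 1.66 in pDCs. That argues against what the skin marker score measures as the cause. The gap of the proliferation list to all genes was 3.70 against at most 1.95 in the other splits drawn (1 of 100 as large, with the real one), without adjustment over lists. Division of the tumour cells is a candidate explanation that was not tested apart from division of other cells in the biopsies.

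Of 41 surface and secreted markers of pDCs, 25 were lower in BPDCN and 16 not called. The list was called lower with the preset correlation but not with an estimated one (camera adjusted p = 0.188). With the tissue score as covariate the list median was -1.90 (-2.87 without BPDCN replicate 9), in a fit where the scores of the groups did not overlap. Across tumours with scores of -0.50 to 6.33 the list mean was 4.86 to 6.93 log2 CPM, against 8.38 to 8.54 in pDCs. It did not fall as the score rose (r = 0.288, permutation p = 0.373). That argues against dilution by the skin cells that this score tracks as the whole cause. The spread of 2.03 over the middle 50% of members passed its preset limit but cannot decide this, since other cells may also express members. The gap of the pDC surface list to all genes was -1.82 against at most 1.49 in size in the other splits drawn (1 of 100 as large, with the real one), without adjustment over lists. A lower programme in the tumour cells and dilution by T cells or other blood cells stay open and may both contribute.

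Single libraries lay far from the others of their group in 38 of 374 values tested. Chance gives about 1 in 20 for independent, normally distributed values. The values tested are not independent, since lists and named genes share members, and some lie at 0 counts. The excess is therefore no measure of how many libraries depart. Values are log2 CPM, or list means of it, unless said otherwise. BPDCN replicate 9 was lowest for fibroblasts (1.40), endothelial cells (-0.10), the BCL2 family (3.54), DCN (3.21), DPT (2.28), NNMT (0.258), SFRP2 (-1.10), IFI27 (0.666), TADA3 (5.56), ACKR1 (-0.949) and ECSCR (-1.82), and highest for ZEB2 (8.08) and PHC3 (8.37). BPDCN replicate 8 was lowest for pDC surface markers (4.86), SWI/SNF complexes (5.10), TLR9 (1.05), PRPF40B (1.525) and KMT2B (4.28), and highest for CD1E (10.33). BPDCN replicate 1 had the lowest TMM factor (0.745), RB1 (2.195) and MYLIP (3.23), and the highest IL3RA (9.63) and RPS19 (13.46). BPDCN replicate 5 was lowest for NCAM1 (5.37) and BPDCN replicate 2 for CSPG4 (0.229).

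Among the pDC libraries, replicate 1 was lowest for MCL1 (9.66) and AURKB (-4.35) and highest for TPSAB1 (-3.06). Replicate 2 was highest for TADA3 (6.40), BCL7C (3.75), ECSCR (-3.22) and SLC4A1 (-1.98). Replicate 3 was lowest for the tumour suppressor list (5.61) and highest for histone lysine demethylases (5.79) and GZMB (10.88). Replicate 4 was highest for proliferation (1.66) and lowest for FUT7 (6.19). The AURKB value stands for 0 counts, and ECSCR and TPSAB1 had no counts in the other pDC libraries, so these values lie at the floor.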

How the results depend on the processing

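Removal of the length trend, the covariate fit without BPDCN replicate 9 and omission of BPDCN replicates 1 and 9 were chosen only after the results were seen. Higher and lower genes numbered 3266 and 1090 with glmTreat, 1102 and 459 with the tissue score as covariate, and 1488 and 963 in that fit without BPDCN replicate 9; voom called 5752 lower genes. Other settings stayed within 1.5 times the counts of 5131 and 3294. Called lists numbered 11 with the tissue score, 13 without the other-cell genes (whose own lists are then not tested), 0 with an estimated correlation 26 with fry in 1 direction and 37 with fry for change in either direction, against 21; glmTreat gives no list test. Leaving out single libraries gave 4220 to 5774 higher genes, 2458 to 4106 lower genes, 19 to 22 lists and a tissue score difference of 4.85 to 5.71. With the tissue score the medians of 11 lists changed sign, 3 of them called: ribosomal (-0.0015), keratinocyte (-3.15), and sweat gland and adipose (-0.37). So did the called genes PCGF2 (-2.39), HR (-2.89), TADA3 (-0.11), RPL35 (-0.28), RPS19 (-0.067), TYRP1 (-1.68), MUCL1 (-1.22) and SDC1 (-0.89). Without BPDCN replicate 9 that fit gave -4.13 for keratinocytes, -0.15 for mast cells, -0.12 for sweat gland and adipose, PCGF2 -0.027, CBX2 -0.61, PRMT2 0.027, HR -1.99, TYRP1 -1.35, MUCL1 -0.57 and SDC1 -3.01, while TADA3 (1.34), RPL35 (2.13), RPS19 (1.84) and the ribosomal list (1.47) were positive again. The score is built from keratinocyte, fibroblast and endothelial genes, so these are adjusted for themselves; for the others the cause was not tested. Of the 143 named genes 38 lost their call with glmTreat, and at most 4 under any scaling, tool or filter. In the simulation 2% of 2-fold and 47% of 4-fold changes were recovered. Only 200 genes were changed there, far fewer than were called in the real data, so these shares need not hold for it.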

Other observations

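The tests in this part were chosen only after the results were seen, and its genes were picked after their values were seen. Called in the fit without covariate, in the fit with the tissue score and in every fit with a library left out were 990 higher and 325 lower genes. Members of the fibroblast and matrix list, such as DCN, DPT, LUM and COL3A1, were among the higher genes, so passing these fits does not free a gene of skin signal. SERPINB2, a serine protease inhibitor, stood at 568 ± 389 CPM (SD, n = 9) in BPDCN and 1.58 ± 0.631 (n = 4) in pDCs, a log2 fold change of 8.49 ± 0.846 (edgeR adjusted p = 6.93e-06). HES6, a transcription factor of the Notch pathway, stood at 321 ± 156 against 3.02 ± 0.948 CPM (6.73 ± 0.599, edgeR adjusted p = 2.58e-06). CADM1, an adhesion molecule, stood at 51.4 ± 21.8 against 0.409 ± 0.181 CPM. LRRC36 stood at 2.68 ± 0.731 against 87.2 ± 5.01 CPM (-5.02 ± 0.237, edgeR adjusted p = 1.15e-08). KLF6, an early response transcription factor, stood at 121 ± 28.8 against 1281 ± 363 CPM.

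BPDCN replicate 9 had the lowest tissue score of the tumours (-0.50), and CSPG4 stood there at 133 CPM, OCA2 at 26.5, CXCL12 at 56.4 and CCL21 at 44.3. In BPDCN replicate 8, CCL19 stood at 639 CPM, LUM at 468, CCL21 at 194, CLEC9A at 21.4 and CD1A at 21.4. The dendritic cell markers XCR1 and CD207 stood there at only 0.218 and 0.827 CPM, against 4.52 and 13.3 in BPDCN replicate 7.

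Across the 9 tumours the tissue score was set against the mean of 36 other lists by exact permutation. It correlated with smooth muscle genes (r = 0.986, p = 5.51e-06, adjusted p = 0.000198; rho = 0.983, p = 4.96e-05, adjusted p = 0.00179; r = 0.962 without the 2 tumours farthest from the median). Melanocyte genes gave r = 0.869 (permutation p = 0.00178, adjusted p = 0.0213), rho = 0.95 (p = 0.000353, adjusted p = 0.00635) and r = 0.98 without those tumours. Mast cell genes gave r = 0.869 (permutation p = 0.000559, adjusted p = 0.0101), rho = 0.917 (p = 0.00131, adjusted p = 0.0157) and r = 0.869 without them. No other list passed, among them pDC surface markers (r = 0.288, permutation p = 0.373, adjusted p = 0.747, and rho = 0.283, p = 0.463) and proliferation (r = -0.035, permutation p = 0.927, adjusted p = 0.937, and rho = -0.0833, p = 0.843). Without the 2 farthest tumours r was 0.689 for pDC surface markers and -0.0786 for proliferation. For sweat gland and adipose genes it was 0.917, against 0.598 over all 9.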
